A study of Mus musculus with 12 samples.

How the data were processed

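Striatum was dissected from 90-day-old male mice, total RNA was isolated with Trizol and checked by spectrophotometry and gel electrophoresis, and biotin-labelled single-stranded cDNA was made for Affymetrix whole-transcript arrays. The 12 arrays comprised 3 from each combination of 2 Htt knock-in alleles (Q20 and Q111, both homozygous) and 2 Grm5 genotypes (both copies or none). The deposited values are log2 signals that the authors made with RMA, which corrects background, equalizes the probe distributions of the arrays by quantiles and summarizes the probes of each set by median polish. The submitters' notes name Partek and RMA without versions, and the series description names Partek Genomics Suite 6.5. The values were not centred per gene and ranged over log2 signals typical of RMA, which was tested on the table. The authors' stated criteria were an ANOVA p below 0.05 and a change of at least 1.5-fold.

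The table held 35556 probe sets. Platform annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 12146, and the 21789 described 19938 genes. Each gene was represented by the probe set with the highest mean over the 12 arrays. Genes were tested when that set lay above the 25th percentile of its array in at least 3 arrays, which left 16721. Gene order came from RefSeq on GRCm38.p6, in which 91 of the named sets had no match, and it was used for naming and for neighbours alone. Genes not represented among these were not analysed here.

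Each gene was fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group over all 12 arrays, leaving 8 residual degrees of freedom and a prior of 6.88. The 8 contrasts were the effect of the Q111 allele with and without mGluR5, the effect of mGluR5 loss in Q20 and in Q111 mice, their interaction, the double mutant against the double control, and the 2 average effects. Tests were two-sided with Benjamini-Hochberg adjustment over the tested genes, and a gene was called at an adjusted p below 0.05. Errors of log2 fold changes are standard errors of limma. On simulated data 71% of 200 genes altered 1.5-fold were recovered in the effect of the Q111 allele with mGluR5 among 16721 genes, with 7 false calls, and 95.5% at 2-fold with 13, while in the average effect of the allele 92% and 98.5% were recovered with 21 and 8 false calls. Each setting was simulated 1 time with genes and arrays drawn independently. The simulated arrays therefore lack the array-wide spread of the real ones, where recovery and false calls may differ. Array data hold no counts, and the number of arrays limits the precision.

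The groups, contrasts, gene lists and the rule for naming genes were set before the data were examined. The rule took Grm5 and Htt, the 12 largest rises and the 12 largest falls of each contrast among called genes, the 3 members with the smallest unadjusted p of each list that is described, and up to 5 called neighbours on either side of each targeted gene. Predicted genes, olfactory and vomeronasal receptors and small non-coding RNA genes were counted but not named. The 22 lists held 554 gene names, of which 487 were tested. They covered striatal projection neuron identity, direct-pathway and indirect-pathway markers, immediate early genes, glutamate receptors without Grm5, partners of group I metabotropic receptors, GABA genes, synaptic vesicle proteins, oxidative phosphorylation subunits, chaperones, cholesterol synthesis and the interferon response, and markers of oligodendrocytes and myelin, astrocytes, microglia, endothelial and mural cells (vascular markers), choroid plexus, ependymal cells, cortical projection neurons, thalamus with hypothalamus and septum, striatal interneurons and blood. Each list was tested in each contrast with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with a correlation estimated from the data. With the estimated correlation no list was called in any contrast.

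Effects were compared by correlation across genes and by their shared called genes. The 100 tested genes on either side of Grm5 and Htt were compared with all others by Fisher's exact test. Alternatives covered the authors' criteria, an unmoderated model, an intensity trend, a fold minimum, fits on the compared groups alone and the replicate number as a block. They also covered array weights, median centring, quantile normalization, the filter, the choice of probe set, all probe sets in place of genes, and leaving out each array. A covariate for the interquartile range of each array and a fit without the 2 arrays at the ends of the first principal component were added after the data were seen. Both of those arrays came from Q111 mice with mGluR5 (replicates 2 and 3). That fit therefore kept 1 array of this group. Its counts and p-values are listed with the other alternatives alone, and no conclusion about calls is drawn from them. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.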

Results

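RNA abundance was measured in the striatum of 90-day-old male mice with whole-transcript microarrays. The mice carried a knock-in Huntington's disease gene, either the control Q20 allele or the expanded Q111 allele on both chromosomes, and had either both copies of Grm5, the gene of the metabotropic glutamate receptor mGluR5, or neither. The 12 arrays formed 4 groups of 3, which were Q20 mice with mGluR5, Q20 mice without mGluR5, Q111 mice with mGluR5 and Q111 mice without mGluR5. The labels state a mixed genetic background of 129, CD-1, C57BL/6 and FV mice. They do not state whether the 3 arrays of a group came from separate animals, so the p-values measure the spread between these samples. Array medians lay between 7.05 and 7.16 on the log2 scale, and the number of arrays limits the precision of each value. The arrays also differed in how widely their values spread. The mean interquartile range was 2.80 ± 0.08 (SD, n = 3) in Q20 mice with mGluR5, 2.83 ± 0.12 in Q20 mice without it. It was 2.73 ± 0.19 in Q111 mice with mGluR5 and 2.74 ± 0.07 in Q111 mice without it. The first principal component, with 36.5% of the variance, followed this range over the 12 arrays (Pearson r = 0.991 and Spearman rho = 0.979, two-sided permutation p = 1e-05 for each, the smallest that the permutations can give). Pearson r was 0.992 without the 2 arrays whose range lay farthest from the median. In each of the 4 groups replicate 2 had the widest range.

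Predicted genes, olfactory and vomeronasal receptors and small non-coding RNA genes were counted but not named, so that the largest changes given below are those of the other genes. Group means below the 25th percentile of the arrays (5.69 to 5.94), the level of the filter, are not told from background, so that changes from or to them have no exact size or rank. Among named genes called in a comparison this held for AI506816 and Aoah in all groups but Q111 mice with mGluR5, and in 1 or 2 groups for Trhr, Impg1, Mcmdc2, Tmem74, Mpzl2, Slc38a11 and Tlr1. The targeted genes were read first. Grm5 (Entrez 108071, chromosome 7 in GRCm38.p6) was lower in mGluR5 knockouts. It averaged 12.00 ± 0.07 (SD, n = 3) in Q20 mice with mGluR5 against 11.06 ± 0.12 without, and 11.94 ± 0.08 in Q111 mice with mGluR5 against 11.07 ± 0.08 without. The fall was 0.94 ± 0.09 (SE) log2 units in Q20 mice (1.92-fold, limma adjusted p = 0.000189) and 0.87 ± 0.09 in Q111 mice (1.83-fold, adjusted p = 0.00017). All 6 knockout arrays lay below all 6 others, with a gap of 0.68, wider than the 0.24 that separated the most distant arrays of a single mGluR5 genotype. The signal in knockouts stayed well above the middle of the array, and which probes of the Grm5 probe set lie in the deleted part of the gene is not known. Htt (Entrez 15194, chromosome 5), which encodes huntingtin, was 0.15 ± 0.06 log2 units lower in Q111 mice on average, a difference that did not pass the test (limma adjusted p = 0.344), although all 6 Q111 arrays lay below all 6 Q20 arrays by a gap of 0.02.

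**Figure D1:**
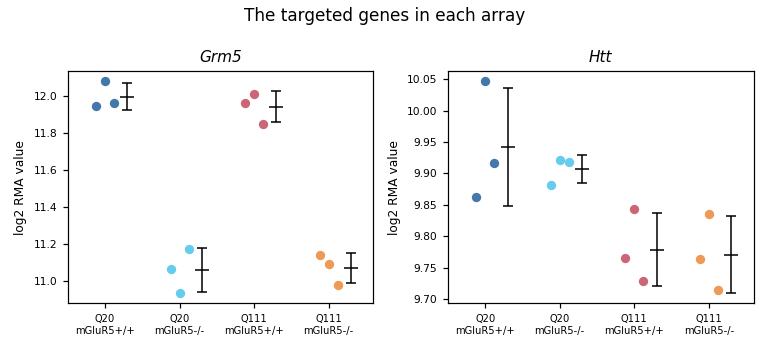
RMA log2 values of Grm5 (left) and Htt (right), with 1 point per array for the 4 groups and the mean and SD of the 3 arrays beside them. The lowest Grm5 value with mGluR5 was 11.85 and the highest without it 11.17, while Htt ranged from 9.71 to 10.05.

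The effect of the expanded allele in mice with mGluR5 asks how the Q111 striatum differs when the receptor is present. The largest falls were in Dnah6, an axonemal dynein heavy chain (log2 fold change -2.42 ± 0.13, SE), in Ccl19, a chemokine that guides lymphocytes (-2.15 ± 0.11), in Cdhr1, a cadherin of photoreceptors (-1.82 ± 0.10), and in Rpl26, a ribosomal protein (-1.73 ± 0.15). The largest rises were in the orphan transporter Slc6a16 (1.79 ± 0.10), the B cell co-receptor Cd72 (1.71 ± 0.12) and the cilium-associated Cfap54 (1.61 ± 0.15). AI506816 rose too (2.14 ± 0.20), from a level below the filter. Falls were also seen in H60b, a ligand of natural killer cell receptors (-1.29 ± 0.19), in Ackr1, an atypical chemokine receptor (-1.10 ± 0.10), and in the secreted Wnt inhibitor Sfrp1 (-1.02 ± 0.14). The peptide transporter Slc15a2 (-1.04 ± 0.12), the leukotriene enzyme Lta4h (-1.01 ± 0.18), the ciliary protein Invs (-0.97 ± 0.09) and the centrin Cetn4 (-0.97 ± 0.19) fell too. Further rises were in Nat8f4 (1.14 ± 0.15), the retrovirus restriction factor Fv1 (1.03 ± 0.11), the methylglyoxal-detoxifying enzyme Glo1 (0.93 ± 0.15), and the prostaglandin-degrading enzyme Hpgd (0.93 ± 0.10). Abhd14a (0.90 ± 0.09), Fndc1 (0.90 ± 0.10), the matrix protein Abi3bp (0.85 ± 0.14) and Rpl34 (0.84 ± 0.18) rose, and the pseudogene Nlrp5-ps fell (-1.35 ± 0.13). In total 96 of 16721 tested genes changed, 50 higher and 46 lower (limma, adjusted p below 0.05), of which 72 changed at least 1.5-fold. In all 96 the 3 Q111 arrays lay entirely above or below the 3 Q20 arrays, as they did in 9.69% of all tested genes, where chance gives 10%. Of 95 called genes with a position, 24 had another called gene among the 5 tested genes on either side, where shuffled positions gave 5.18 on average. Strain alleles of the mixed background cannot be told apart from the effect of the Q111 allele here. The count was 35 with an unmoderated linear model, but 266 with the interquartile range of the arrays as a covariate, and 44 to 128 with 1 array left out.

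Genes of the striatal projection neurons, the cells lost in the human disease, did not pass the test as a group in this comparison. None of the 45 measured genes of the identity list passed over all genes and 0 when adjusted over the list alone, 32 were negative, and the camera adjusted p was 0.314. Vascular markers were shifted downward, with 15 of 18 negative and none changed over all genes or when adjusted over the list alone. For this shift camera gave adjusted p = 0.00972, and adjusted p = 0.757 with an estimated correlation, and it was lost without replicate 1 of the Q20 or replicate 2 of the Q111 mice with mGluR5 (adjusted p = 0.133 and 0.302). Among them were Tagln (-0.31 ± 0.13, SE) and Flt1 (-0.23 ± 0.10), which did not pass. Markers of thalamus, hypothalamus and septum were also shifted downward, 13 of 17 negative (camera adjusted p = 0.0381). The camera adjusted p was 0.757 with an estimated correlation and 0.0534 with the replicate number as a block. Replicate 1 of the Q20 mice with mGluR5 had a list mean of 7.33 against 6.97 to 7.10 in the other 11 arrays, and the call was lost without it (adjusted p = 0.738), as in 3 of 12 cases with 1 array left out. The ion channel Trpc4 fell (-0.55 ± 0.11) and was the member called over all genes, against 2 adjusted over the list alone. Myelin markers were shifted upward, 14 of 18 positive with none called over all genes or adjusted over the list alone (adjusted p = 0.0381, and adjusted p = 0.999 with an estimated correlation). Mog stood at 0.28 ± 0.10 and Mag at 0.24 ± 0.11. The direction of the list turned downward without the arrays at both ends of the first principal component, a fit that left 1 array of the Q111 group. The call was lost with the replicate number as a block (camera adjusted p = 0.0609). It was lost too without replicate 2 of the Q20 mice with mGluR5 (0.873), whose list mean of 9.66 was the lowest of the 12. Leaving out replicates 2 and 3 of the Q111 mice with mGluR5 (0.316 and 0.123) or the filter (0.120) also ended it. Single members of other lists fell, namely Gabra2, a GABA-A receptor alpha subunit (-0.67 ± 0.09), the sterol enzyme Hsd17b7 (-0.64 ± 0.12) and the vesicular glutamate transporter Slc17a8 (-0.52 ± 0.10). For cholesterol synthesis the median of the log2 changes was positive (0.04) while the mean (-0.02) and the test pointed down, with adjusted p = 0.999.

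The same allele was then compared in mice without mGluR5. Ccl19 (-2.06 ± 0.11, SE), Cdhr1 (-1.78 ± 0.10), H60b (-1.62 ± 0.19), Rpl26 (-1.53 ± 0.15) and Ackr1 (-1.11 ± 0.10) fell here too, and Cd72 (1.63 ± 0.12) and Nat8f4 (1.12 ± 0.15) rose. Dnah6 rose (2.59 ± 0.13) and Cfap54 fell (-1.49 ± 0.15), each opposite to its change in mice with mGluR5. Serpina3n, a secreted protease inhibitor known from reactive astrocytes, rose (1.60 ± 0.12), as did the lipid phosphodiesterase Gdpd3 (2.42 ± 0.32), Nt5dc3 (1.76 ± 0.13) and Catspere2 (1.28 ± 0.17). The phospholipase Pla2g4e (1.08 ± 0.11), the protease Klk6 (1.01 ± 0.15), the Ras activator Rasgrp3 (0.88 ± 0.17) and the protocadherins Pcdhb3 (0.87 ± 0.19) and Pcdhb8 (0.84 ± 0.13) rose as well. Other falls were in the securin Pttg1 (-1.82 ± 0.12), Tmem267 (-1.52 ± 0.15), the microtubule-nucleation protein Mzt1 (-1.36 ± 0.27), the phosphatase Ublcp1 (-1.23 ± 0.11), the aldehyde dehydrogenase Aldh7a1 (-1.17 ± 0.19) and the endothelial receptor Acvrl1 (-1.17 ± 0.09). In total 148 genes changed, 57 higher and 91 lower (limma, adjusted p below 0.05), 84 of them at least 1.5-fold. In all 148 the groups of 3 did not overlap, as in 19.1% of all tested genes against 10% by chance. A called gene lay among the 5 tested genes on either side of 39 of the 147 with a position, against 12.36 in shuffles. Here too strain alleles cannot be told apart from the effect of the Q111 allele. Leaving out 1 array at a time gave between 74 and 232 genes, the lowest without replicate 1 of the Q20 mice lacking mGluR5 and the highest without replicate 2 of the Q111 mice with mGluR5, and the covariate for the interquartile range gave 353.

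Vascular markers were again shifted downward in mice without mGluR5, with 16 of 18 negative, 1 changed over all genes and 9 adjusted over the list alone. Camera gave them adjusted p = 0.00124, and adjusted p = 0.916 with an estimated correlation. The potassium channel subunit Abcc9, found in pericytes, fell (-0.46 ± 0.08, SE), while the transporter Slco1a4 stood at 0.64 ± 0.14 without passing over all genes. Myelin markers were shifted upward, 12 of 18 positive, 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.0238, and adjusted p = 0.916 with an estimated correlation). Their call was lost in 3 of 12 cases with 1 array left out, namely replicates 1 and 3 of the Q20 and replicate 2 of the Q111 mice without mGluR5 (adjusted p = 0.143, 0.111 and 0.0728). GABA genes (14 of 17 negative) and chaperones (23 of 29 negative) were shifted downward, each with adjusted p = 0.0332 and with adjusted p = 0.916 with an estimated correlation. Neither list held a called gene over all genes or adjusted over the list alone. Both shifts were lost with quantile normalization (adjusted p = 0.234 and 0.146) and with the interquartile range of the arrays as a covariate (adjusted p = 0.345 for each), and in 4 and 3 of 12 cases with 1 array left out. Of the projection neuron identity list 0 of 45 passed over all genes and 4 adjusted over the list alone (camera adjusted p = 0.78). These included Rxrg, a retinoid receptor (-0.39 ± 0.09), and the opioid precursor Pdyn (-0.64 ± 0.15). The indirect-pathway marker Plxdc1 rose (0.52 ± 0.11). Grm7, another metabotropic glutamate receptor (-0.46 ± 0.09), Sdhd, a subunit of respiratory complex II (-0.45 ± 0.10), and Hsd17b7 (-0.79 ± 0.12) fell. Oxidative phosphorylation subunits and immediate early genes had a negative median and mean where the test pointed up (adjusted p = 0.667 and 0.875).

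Loss of mGluR5 in Q20 mice was examined on a striatum with the control allele. Strain alleles of the mixed background cannot be told apart from it here. Beside Grm5, the largest falls were in Dnah6 (-2.66 ± 0.13, SE), Nt5dc3 (-1.69 ± 0.13), the protocadherins Pcdhb6 (-1.02 ± 0.17) and Pcdhb3 (-0.96 ± 0.19) and Nlrp5-ps (-0.997 ± 0.13). Trhr, the receptor of thyrotropin-releasing hormone, fell to a level below the filter (-0.996 ± 0.19). The lysosomal enzyme Idua (-0.98 ± 0.10), the keratin Krt12 (-0.91 ± 0.13), Sfrp1 (-0.88 ± 0.14), Fam163a (-0.78 ± 0.10) and the scaffold protein Iqgap2 (-0.78 ± 0.12) also fell. Cfap54 (1.27 ± 0.15), Serpina3n (1.11 ± 0.12), Rpl34 (1.06 ± 0.18), Aldh7a1 (1.06 ± 0.19), Hpgd (1.05 ± 0.10), Tmem267 (0.99 ± 0.15) and the neurokinin receptor Tacr3 (0.96 ± 0.15) rose. So did Timmdc1 (0.87 ± 0.14), Baalc (0.84 ± 0.13), Fut10 (0.82 ± 0.11), the unconventional myosin Myo7a (0.80 ± 0.09) and Hhipl1 (0.78 ± 0.09). In total 50 genes changed, 23 higher and 27 lower (limma, adjusted p below 0.05), 42 at least 1.5-fold. Oxidative phosphorylation subunits were shifted upward, with 55 of 71 positive, 0 called over all genes and 2 adjusted over the list alone. Their camera adjusted p was 0.000331, and adjusted p = 0.837 with an estimated correlation. Among them Ndufc2 stood at 0.45 ± 0.09 and Cox6c at 0.33 ± 0.08. Microglia markers were shifted upward, 15 of 19 positive with 0 called over all genes and 0 adjusted over the list alone. GABA genes were shifted upward too, 16 of 17 positive with 0 called over all genes and 1 adjusted over the list alone, each with adjusted p = 0.0144 and with adjusted p = 0.837 with an estimated correlation. The GABA shift was not called with quantile normalization (adjusted p = 0.0615), nor the microglia shift with the interquartile range as a covariate (adjusted p = 0.0553). All 3 calls were lost without replicate 2 of the Q20 mice lacking mGluR5 (adjusted p = 0.646, 0.499 and 0.270 for oxidative phosphorylation, microglia and GABA genes), which had the highest mean of the 12 arrays for each of these lists (10.29, 8.56 and 10.66). The microglia call ended in 3 of 12 cases with 1 array left out, and the GABA call in 2. Abcc9 rose (0.46 ± 0.08). Medians and means were slightly positive where the test pointed down for projection neuron identity, indirect-pathway markers and glutamate receptors, whose camera adjusted p-values were 0.602, 0.602 and 0.686. Leaving out 1 array at a time gave between 25 and 97 genes, an unmoderated linear model 19 and the covariate for the interquartile range 213.

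Loss of mGluR5 in Q111 mice is the comparison in which receptor loss meets the expanded allele. Among the named genes Serpina3n rose most (2.45 ± 0.12 log2 units, SE), followed by Dnah6 (2.35 ± 0.13) and Pla2g4e (1.08 ± 0.11). Trappc2l (0.92 ± 0.11), the electron carrier Cyb5a (0.89 ± 0.12), Myo7a (0.86 ± 0.09), Lrrc10b (0.81 ± 0.16), the kinase Stk10 (0.74 ± 0.10) and Gabra2 (0.72 ± 0.09) came next. The class I histocompatibility gene H2-Q2 (0.59 ± 0.11), the direct-pathway marker Eya1 (0.58 ± 0.11) and Entpd4 (0.57 ± 0.10) rose as well. The largest falls were in Cfap54 (-1.83 ± 0.15), Slc6a16 (-1.80 ± 0.10), Pttg1 (-1.68 ± 0.12) and Acvrl1 (-1.15 ± 0.09), and AI506816 fell to a level below the filter (-2.59 ± 0.20). The photoreceptor matrix protein Impg1 (-1.12 ± 0.13), Abhd14a (-1.01 ± 0.09), Fv1 (-0.96 ± 0.11), the lipase Aoah (-0.91 ± 0.13), Grm5, Mcmdc2 (-0.83 ± 0.10) and Abi3bp (-0.82 ± 0.14) also fell. In total 46 genes changed, 19 higher and 27 lower (limma, adjusted p below 0.05), 39 at least 1.5-fold. Oxidative phosphorylation subunits were shifted upward, 60 of 71 positive with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 9.69e-05, and adjusted p = 0.978 with an estimated correlation). Without replicate 3 of the Q111 mice with mGluR5, which had the lowest list mean of all arrays (9.93), the call was lost (adjusted p = 0.164). Immediate early genes, which respond to neuronal activity, were shifted downward, 24 of 35 negative with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.00405, and adjusted p = 0.978 with an estimated correlation). Among them were Egr1 at -0.27 ± 0.10 and Dusp1 at -0.36 ± 0.16. Their call was lost without replicates 1 or 2 of the Q111 mice with mGluR5 or replicate 1 of those without (adjusted p = 0.143, 0.266 and 0.317). Median, mean and test differed in sign for markers of the direct pathway, microglia, ependymal cells, cortical projection neurons and striatal interneurons, with adjusted p-values of 0.985, 0.701, 0.701, 1 and 0.701. In all 50 genes called in Q20 mice and all 46 called in Q111 mice the groups of 3 did not overlap, as in 12.8% and 7.46% of all tested genes, against 10% by chance. Another called gene lay among the 5 tested genes on either side of 6 of the 50 and 4 of the 46. Shuffled positions gave 1.43 and 1.215 (permutation p = 0.03 and 0.1). In Q111 mice too, strain alleles cannot be told apart from mGluR5 loss. The count in Q111 mice was 23 with an unmoderated linear model, but 150 with the interquartile range as a covariate, and 28 to 52 with 1 array left out.

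The interaction tests whether the effect of the expanded allele differs between mice with and without mGluR5. It was positive, that is higher without the receptor, for Dnah6 (5.01 ± 0.19 log2 units, SE), Nt5dc3 (1.62 ± 0.18), and the muscle protein Tnni1 (1.56 ± 0.28). The adhesion proteins Pcdhb6 (1.48 ± 0.24), Pcdhb2 (1.48 ± 0.26), Pcdhb3 (1.45 ± 0.26) and Pcdhb11 (1.14 ± 0.18), Nlrp5-ps (1.46 ± 0.18), Trhr (1.34 ± 0.27), Serpina3n (1.34 ± 0.17), Lta4h (1.30 ± 0.25) and Rasgrp3 (1.21 ± 0.24) were positive as well. It was negative for Cfap54 (-3.10 ± 0.21), AI506816 (-2.64 ± 0.28, with 3 of 4 groups below the filter), Pttg1 (-1.76 ± 0.17), Slc6a16 (-1.74 ± 0.14), Tacr3 (-1.59 ± 0.21) and Aldh7a1 (-1.56 ± 0.27). Rpl34 (-1.42 ± 0.25), Tmem74 (-1.40 ± 0.22), Abhd10 (-1.34 ± 0.16), Impg1 (-1.30 ± 0.18), Timmdc1 (-1.29 ± 0.20) and the peptidase Cpq (-1.28 ± 0.16) were negative as well. In total 73 genes passed, 36 positive and 37 negative (limma, adjusted p below 0.05). Of them 22 were called for the allele with mGluR5 alone, 34 without it alone, 6 in both with opposite signs and 11 in neither. A single group stood apart in 29 of the 73, where the means of the other 3 spanned less than 1/3 of the whole range, for example Slc6a16 in Q111 mice with mGluR5 and Pttg1 in Q111 mice without it. Markers of thalamus, hypothalamus and septum formed the single list that shifted, upward, with 11 of 17 positive, 0 called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.898 with an estimated correlation). Its member Prkcd stood at 1.11 ± 0.29, and the shift was not called with the interquartile range as a covariate (adjusted p = 0.0601) or in 4 of 12 cases with 1 array left out, among them replicate 1 of the Q20 mice with mGluR5 (adjusted p = 0.313). Myelin and interneuron markers had negative medians and means where the test pointed up (adjusted p = 0.765 and 0.854). Of the 73 genes, 18 had another such gene among the 5 tested genes on either side, which shuffled positions gave for 3.09 on average. The count was 19 with an unmoderated linear model, but 153 with the interquartile range as a covariate and 165 with the authors' criteria, and 34 to 69 with 1 array left out.

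**Figure D2:**
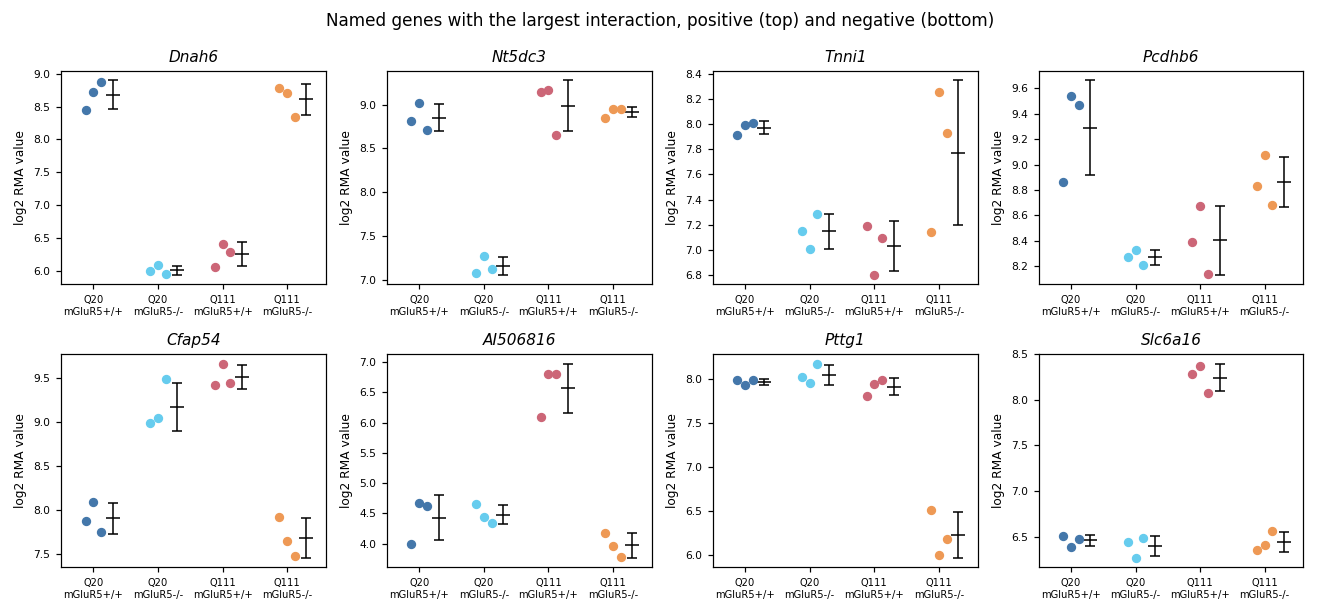
RMA log2 values of the 4 named genes with the largest positive interaction (top) and the 4 with the largest negative interaction (bottom), with 1 point per array and the mean and SD of the 3 arrays of each group. Dnah6 was low in Q20 mice without mGluR5 and in Q111 mice with it, Pttg1 was low in Q111 mice without mGluR5, and Slc6a16 and AI506816 were high in Q111 mice with mGluR5.

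The double mutant, with the expanded allele and without mGluR5, was compared with the double control. Serpina3n rose most (2.71 ± 0.12 log2 units, SE), ahead of Cd72 (1.68 ± 0.12), Gdpd3 (1.58 ± 0.32), Catspere2 (1.18 ± 0.17), and Nat8f4 (1.12 ± 0.15). Pla2g4e (1.07 ± 0.11), Hpgd (1.01 ± 0.10), Trappc2l (0.95 ± 0.11), Baalc (0.88 ± 0.13), Klk6 (0.86 ± 0.15), Dpy19l1 (0.85 ± 0.12) and Stk10 (0.76 ± 0.10) rose too. The largest falls were in Ccl19 (-1.97 ± 0.11), Cdhr1 (-1.89 ± 0.10), Pttg1 (-1.74 ± 0.12), H60b (-1.66 ± 0.19) and Rpl26 (-1.56 ± 0.15). Mzt1 (-1.31 ± 0.27), Acvrl1 (-1.23 ± 0.09), Ublcp1 (-1.17 ± 0.11), Ackr1 (-1.07 ± 0.10), Rabl2 (-0.98 ± 0.20), Invs (-0.98 ± 0.09) and Grm5 (-0.93 ± 0.09) fell too. In total 93 genes changed, 40 higher and 53 lower (limma, adjusted p below 0.05), 62 at least 1.5-fold. In all 93 the groups of 3 did not overlap, as in 14.2% of all tested genes against 10% by chance. A called gene lay among the 5 tested genes on either side of 18 of the 92 with a position, against 4.88 in shuffles. Strain alleles cannot be told apart from the 2 targeted changes in this comparison. Oxidative phosphorylation subunits were shifted upward, 55 of 71 positive, 1 called over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000102, and adjusted p = 0.975 with an estimated correlation). Atp5g1, an ATP synthase subunit, rose (0.49 ± 0.10). Myelin markers were shifted upward, 14 of 18 positive with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.975 with an estimated correlation). Without replicate 2 of the Q20 mice with mGluR5 that call was lost (adjusted p = 0.493). Interferon response genes were shifted upward, 14 of 19 positive with 0 called over all genes and 2 adjusted over the list alone (adjusted p = 0.00216, and adjusted p = 0.59 with an estimated correlation). Ifit1 stood at 0.52 ± 0.12. The interferon genes were not called with quantile normalization (adjusted p = 0.0597). Grm7 (-0.62 ± 0.09) and Hsd17b7 (-0.59 ± 0.12) fell. Median, mean and test differed in sign for indirect-pathway, cholesterol, microglia, choroid plexus and blood genes, each with adjusted p = 0.814, and for synaptic vesicle proteins with adjusted p = 0.975. An unmoderated linear model gave 40 genes, the covariate for the interquartile range 287, and leaving out 1 array at a time between 49 and 163.

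**Figure D3:**
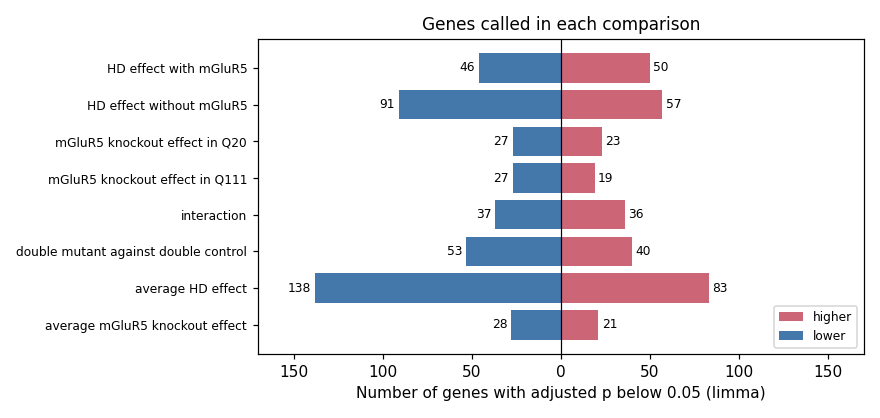
Number of genes with a limma adjusted p below 0.05 in each of the 8 comparisons among 16721 tested genes, with bars to the right for genes that were higher and to the left for genes that were lower. The longest bars belong to the average HD effect, with 83 higher and 138 lower.

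Averaged over both mGluR5 genotypes, with 6 arrays on each side, the genes that fell in Q111 mice included Ccl19 (-2.10 ± 0.08 log2 units, SE), Cdhr1 (-1.80 ± 0.07), Rpl26 (-1.63 ± 0.11), H60b (-1.46 ± 0.13), Ackr1 (-1.11 ± 0.07) and Invs (-0.91 ± 0.06). Each was lower in all 6 Q111 arrays than in any Q20 array. Cd72 (1.67 ± 0.08), Gdpd3 (1.85 ± 0.23), Nat8f4 (1.13 ± 0.10), Klk6 (0.87 ± 0.11), Catspere2 (0.83 ± 0.12), Dpy19l1 (0.72 ± 0.08), the receptor tyrosine kinase Ror1 (0.68 ± 0.11) and Mpzl2 (0.67 ± 0.10) rose. Each was higher in all 6 Q111 arrays. Other falls with separate arrays were in Epm2a, the glycogen phosphatase laforin (-0.87 ± 0.09), and the dynactin subunit Dctn3 (-0.86 ± 0.09). Mzt1 (-0.89 ± 0.19) and Cetn4 (-0.86 ± 0.14) fell with overlapping arrays. Nt5dc3 (0.95 ± 0.09), Serpina3n (0.93 ± 0.09), Slc6a16 (0.92 ± 0.07), AI506816 (0.81 ± 0.14), Tmem267 (-0.96 ± 0.11) and Pttg1 (-0.94 ± 0.08) were called as well, but also in the interaction, so that their average joins unlike effects. In total 221 genes changed, 83 higher and 138 lower (limma, adjusted p below 0.05), 49 at least 1.5-fold. The arrays of the 2 alleles did not overlap in 114 of the 221, and in 1.21% of all tested genes, where chance gives 0.216%. Of 219 called genes with a position, 72 had another called gene among the 5 tested genes on either side, which shuffled positions gave for 27.02 on average. Leaving out 1 array at a time gave between 119 and 511 genes, the highest without replicate 2 of the Q111 mice with mGluR5, and the count was 123 with an unmoderated linear model and 488 with the interquartile range of the arrays as a covariate.

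**Figure D4:**
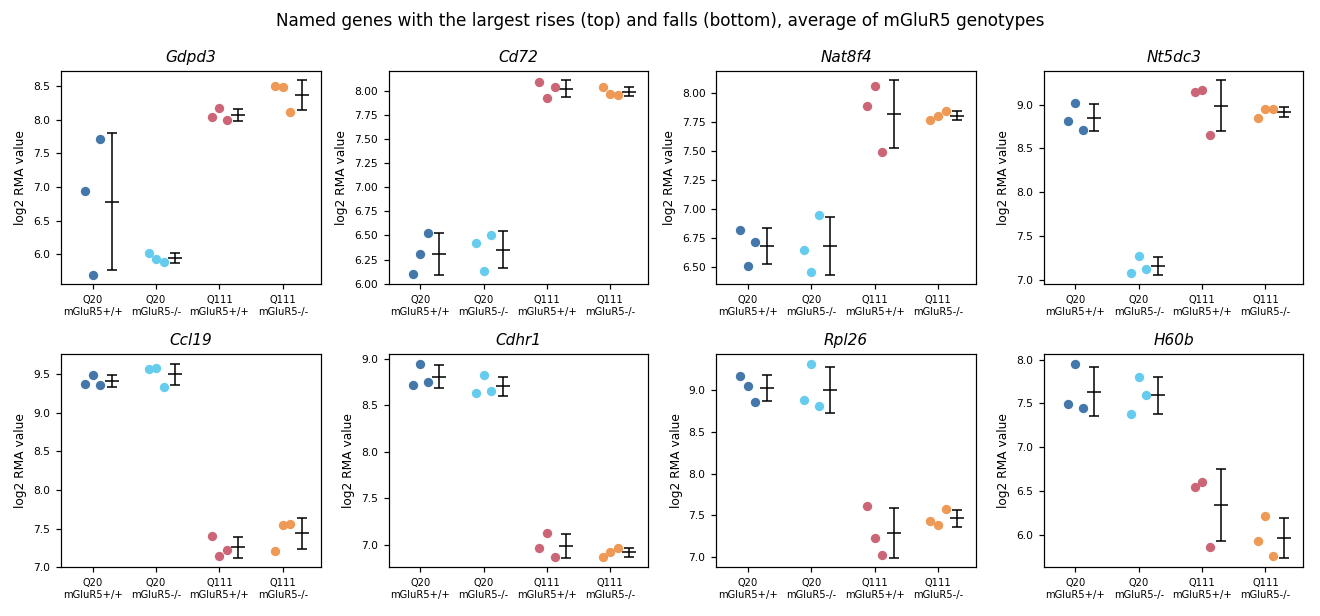
RMA log2 values of the 4 named genes with the largest average rise (top) and the 4 with the largest average fall (bottom) in Q111 mice, with 1 point per array and the mean and SD of the 3 arrays of each group. Ccl19, Cdhr1, Rpl26 and H60b were lower in all 6 Q111 arrays, and Cd72, Gdpd3 and Nat8f4 higher, whereas Nt5dc3 was low in Q20 mice without mGluR5.

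Projection neuron identity genes did not pass as a list in the average effect. Of the 45 genes 29 were negative, 1 fell over all genes and 5 passed adjusted over the list alone (camera adjusted p = 0.5). The retinoid receptor Rxrg fell (-0.29 ± 0.06, SE), while the striatal genes Strip2 (-0.36 ± 0.09) and Rgs14 (-0.29 ± 0.08) did not pass over all genes. Direct-pathway markers had 11 of 12 negative members, 0 called over all genes and 2 adjusted over the list alone (adjusted p = 0.0796), among them Isl1 (-0.29 ± 0.07) and Pdyn (-0.34 ± 0.10). Indirect-pathway markers had 7 of 12 negative, 0 called over all genes and 1 adjusted over the list alone, with a median and mean below 0 where the test pointed up (adjusted p = 0.925). Vascular markers were shifted downward, 16 of 18 negative with 0 called over all genes and 8 adjusted over the list alone (adjusted p = 5.31e-05, and adjusted p = 0.725 with an estimated correlation). Among these were the receptor Flt1 (-0.29 ± 0.07), Abcc9 (-0.22 ± 0.06) and Pecam1 (-0.26 ± 0.07). Abcc9 did not fall with mGluR5, where it averaged 6.89 in Q20 and 6.91 in Q111 mice, against 7.36 and 6.89 without it. Myelin markers were shifted upward, 13 of 18 positive with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 0.974 with an estimated correlation). Mag stood at 0.26 ± 0.08 and Myrf at 0.19 ± 0.06. The myelin markers were not called without replicate 2 of the Q20 or of the Q111 mice with mGluR5 (camera adjusted p = 0.0999 and 0.0590). Among other lists Grm7 (-0.31 ± 0.07), Gabra2 (-0.40 ± 0.06), Sdhd (-0.33 ± 0.07), Hsd17b7 (-0.71 ± 0.09) and Trpc4 (-0.44 ± 0.08) fell, and Sdhc, the partner of Sdhd in complex II, rose (0.38 ± 0.07). Gabra2 averaged 10.01 in Q111 mice with mGluR5 and 10.72 in those without it, against 10.67 and 10.85 in Q20 mice. Rxrg, Hsd17b7 and Sdhc on chromosome 1, Sdhd on chromosome 9 and Trpc4 on chromosome 3 each had another called gene among the 5 tested genes on either side. Whether strain alleles of the mixed background account for these genes was not tested.

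The remaining lists did not pass in the average effect of the expanded allele. Their camera adjusted p-values were 0.552 for immediate early genes, 0.853 for the other glutamate receptors, 0.343 for signalling partners of group I receptors and 0.108 for GABA genes. They were 0.853 for synaptic vesicle proteins, 0.679 for oxidative phosphorylation, 0.154 for chaperones, 0.552 for cholesterol synthesis and 0.108 for the interferon response. Among markers of other cells they were 0.758 for astrocytes, 0.359 for microglia, 0.952 for choroid plexus, 0.679 for ependymal cells, 0.853 for cortical projection neurons, 0.685 for thalamus, hypothalamus and septum, 0.108 for striatal interneurons and 0.771 for blood. Over the list alone 2 glutamate receptors, 2 GABA genes, 2 oxidative phosphorylation subunits, 2 interneuron markers, 1 signalling partner, 1 vesicle protein, 1 cholesterol gene and 1 thalamus marker passed, and none in the others of these lists. The median or the mean differed in sign from the test for oxidative phosphorylation, choroid plexus, ependymal and cortical markers.

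Averaged over both Htt alleles, the genes that rose in mGluR5 knockouts included Serpina3n (1.78 ± 0.09 log2 units, SE), Myo7a (0.83 ± 0.07), the cytochrome oxidase assembly factor Cox18 (0.58 ± 0.09), the malic enzyme Me2 (0.44 ± 0.08) and Mro (0.42 ± 0.08), each higher in all 6 knockout arrays. Grm5 (-0.91 ± 0.07), Krt12 (-0.73 ± 0.09) and the transporter Slc38a11 (-0.65 ± 0.08) fell, each lower in all 6. Rises with overlapping arrays were in Lrrc10b (0.60 ± 0.11), Hpgd (0.57 ± 0.07) and Pla2g4e (0.54 ± 0.08), and further in Trappc2l (0.53 ± 0.08), Cyb5a (0.48 ± 0.09), Hhipl1 (0.46 ± 0.06) and Gabra2 (0.45 ± 0.06). Falls with overlapping arrays were in AI506816 (-1.27 ± 0.14, with 3 of 4 groups below the filter), Slc6a16 (-0.93 ± 0.07), Nt5dc3 (-0.88 ± 0.09), and Pttg1 (-0.80 ± 0.08). Acvrl1 (-0.61 ± 0.07), Abhd14a (-0.59 ± 0.07), Aoah (-0.56 ± 0.09), Idua (-0.50 ± 0.07) and Mcmdc2 (-0.49 ± 0.07) fell likewise. Of the genes with overlapping arrays all but Lrrc10b, Cyb5a, Gabra2 and Aoah were also called in the interaction, as was Serpina3n, so that their average joins unlike effects. A missing call in the interaction does not show a shared effect. Gabra2 averaged 10.67 with and 10.85 without mGluR5 in Q20 mice, and 10.01 and 10.72 in Q111 mice. Aoah averaged 5.79 and 5.57 in Q20 mice, and 6.54 and 5.63 in Q111 mice. In total 49 genes changed, 21 higher and 28 lower (limma, adjusted p below 0.05), 16 at least 1.5-fold. The arrays did not overlap in 19 of the 49 and in 0.305% of all tested genes, where chance gives 0.216%. Another called gene lay among the 5 tested genes on either side of 6 of the 49, against 1.36 in shuffles (permutation p = 0.03). Leaving out 1 array at a time gave between 29 and 60 genes, an unmoderated linear model 23 and the covariate for the interquartile range 170.

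Oxidative phosphorylation subunits showed the most one-sided list shift of the average knockout effect, upward, with 65 of 71 positive, 1 called over all genes and 2 adjusted over the list alone (camera adjusted p = 1.34e-08, and adjusted p = 0.994 with an estimated correlation). The called member was the complex I subunit Ndufc2 (0.39 ± 0.07, SE), which lies 30 tested genes from Grm5 on chromosome 7. Atp5g1 stood at 0.29 ± 0.07 without passing over all genes. Immediate early genes were shifted downward, 23 of 35 negative with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.994 with an estimated correlation). Npas4, an activity-regulated transcription factor, stood at -0.29 ± 0.11, Junb at -0.20 ± 0.08 and Arc at -0.26 ± 0.11. Interferon response genes were shifted upward, 14 of 19 positive with 0 called over all genes and 2 adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.994 with an estimated correlation). Ddx58 (0.24 ± 0.06) and Ifit1 (0.31 ± 0.09) had the smallest p-values of that list without passing over all genes. Vascular markers (13 of 18 positive, 0 called over all genes and 1 adjusted over the list alone), microglia markers (14 of 19 positive, 0 and 1) and GABA genes (12 of 17 positive, 1 and 2) were shifted upward, each with adjusted p = 0.0414 and with adjusted p = 0.994 with an estimated correlation. Quantile normalization ended these 3 calls (adjusted p = 0.0653, 0.0803 and 0.209), and the covariate for the interquartile range ended those of microglia, GABA and interferon genes (0.183, 0.183 and 0.0719). With the replicate number as a block the vascular, microglia, GABA and interferon calls were lost (camera adjusted p = 0.0592 each). Leaving out 1 array ended the calls of vascular, microglia, GABA and interferon genes in 7, 8, 7 and 6 of 12 cases. Projection neuron identity genes did not pass, with 26 of 45 positive, 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.942). Nor did partners of group I receptors, 24 of 37 positive with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.907). For both of these, and for chaperones and thalamus, hypothalamus and septum markers, the median and mean were above 0 where the test pointed down.

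The effects were then set beside each other. Of the genes called for the expanded allele with or without mGluR5, 33 were called in both, 27 with the same sign and 6 with opposite signs. Of the 27, 8 were higher and 19 lower, where independent calls would share 0.17 and 0.25 genes. The calls are not independent, however, because both comparisons use the same estimate of spread for each gene. Ccl19, Cdhr1, Rpl26, H60b, Ackr1, Cd72 and Nat8f4 were among those with the same sign, and Dnah6 and Cfap54 among those with opposite signs. Across all 16721 genes, which are not independent replicates, the 2 effects correlated with Pearson r = 0.271 and Spearman rho = 0.269. A Pearson r as large in absolute size came from 31 of 100 groupings of the arrays, the real one included. The effects of mGluR5 loss in Q20 and Q111 mice shared 7 called genes, of which 4, including Serpina3n, Myo7a and Grm5, had the same sign. Of these, Grm5 is the targeted gene and Myo7a lies 38 tested genes from it. Across genes they gave r = -0.0156 and rho = 0.0154. The average effects of the expanded allele and of mGluR5 loss shared 24 called genes, 9 with the same sign and 15 with opposite signs. Across genes they gave r = -0.0834 and rho = -0.0760. These 3 correlations were the family computed, and none was given a p-value across genes.

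**Figure D5:**
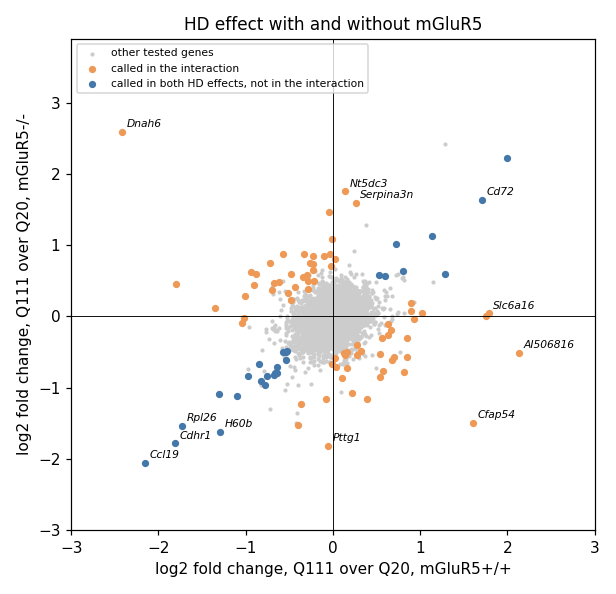
Log2 fold change of Q111 over Q20 mice with mGluR5 (horizontal) against that without mGluR5 (vertical), with 1 point per tested gene, genes called in the interaction in orange and genes called in both effects but not in the interaction in blue. Ccl19, Cdhr1 and Cd72 lie near the diagonal, and Dnah6, at -2.42 and 2.59, and Cfap54, at 1.61 and -1.49, lie across it.

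Because the mice had a mixed background, the genes beside each targeted gene were examined for linked changes. Of the 200 tested genes nearest to Grm5, 100 on either side, 1 was called in Q20 knockouts, 1 in Q111 knockouts and 2 in the average effect. Myo7a, 38 genes away, was called in all 3, and Ndufc2, 30 genes away, in the average. The shares did not pass the test against those among the other genes (two-sided Fisher's exact test, p = 0.446, 0.419 and 0.112). Of the 200 genes nearest to Htt, 0 were called with mGluR5, 1 without and 1 on average (exact p = 0.633, 1 and 0.528). This was Tlr1, an innate immune receptor 98 genes away (average log2 fold change -0.60 ± 0.08, SE). With 50 genes on either side the share near Grm5 in the average effect passed (Fisher's exact p = 0.0334).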

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

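The explanations of patterns below were written after the called genes had been seen. The splits of the arrays, the test without neighbours of the same name family, the test without chromosome 5 and the regroupings for each list were written down before their own result was seen. The tests of neighbouring called genes, of the gap in Grm5 and of the interquartile range as a covariate were chosen after the result was seen.

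The effect of the expanded allele differed between mice with and without mGluR5 in 73 genes by the interaction term, of which 42 had been named. The difference, without minus with mGluR5, was positive in log2 units for Dnah6 (5.01), Nt5dc3 (1.62), Tnni1 (1.56), Pcdhb6 (1.48), Pcdhb2 (1.48), Nlrp5-ps (1.46), Pcdhb3 (1.45), Trhr (1.34), Serpina3n (1.34), Lta4h (1.30), Rasgrp3 (1.21), Pcdhb11 (1.14), Pla2g4e (1.09), Sfrp1 (1.0), Idua (0.97), Slc15a2 (0.95), Pcdhb8 (0.94), Iqgap2 (0.89) and Trappc2l (0.79). It was negative for Cfap54 (-3.10), AI506816 (-2.64), Pttg1 (-1.76), Slc6a16 (-1.74), Tacr3 (-1.59), Aldh7a1 (-1.56), Rpl34 (-1.42), Tmem74 (-1.40), Abhd10 (-1.34), Impg1 (-1.30), Timmdc1 (-1.29), Cpq (-1.28), Abi3bp (-1.15), Tmem267 (-1.12), Acvrl1 (-1.08), Fv1 (-0.98), Hpgd (-0.97), Fut10 (-0.86), Ublcp1 (-0.86), Abhd14a (-0.83), Fndc1 (-0.71), Mcmdc2 (-0.68) and Hhipl1 (-0.65). Markers of thalamus, hypothalamus and septum also differed between the effects with and without mGluR5 (camera adjusted p = 0.02), though not with an estimated correlation (adjusted p = 0.898), with the interquartile range as a covariate (adjusted p = 0.0601) or without replicate 1 of the Q20 mice with mGluR5 (adjusted p = 0.313).

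A signal also appeared in probe sets that the gene comparisons did not use, since 13767 of the 35556 sets have no single gene. All sets were tested without the filter on background. Those without a single gene made up 134 of 218 called sets for the Q111 allele with mGluR5 and 140 of 261 without it. They were 12 of 36 and 27 of 62 for mGluR5 loss in Q20 and Q111 mice, and 28 of 64 for the interaction. For the double mutant they were 143 of 223, and for the average effects of the allele and of mGluR5 loss 282 of 461 and 28 of 58. For mGluR5 loss in Q20 mice this share lay below that of such sets in the table. The largest absolute log2 change among the called sets without a single gene was 4.59 for the allele with mGluR5 and 4.62 for the double mutant.

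Genes called in the average effect of the Q111 allele lay beside one another on the chromosomes more often than shuffled positions gave: 72 of 219 had another among the 5 tested genes on either side, against 27.02 on average (permutation p = 1e-04, the smallest that 10000 shuffles can give). Shared probes between near-identical family members do not account for it, since 68 had such a neighbour of another name family against 25.9 in shuffles. Neither does the signal range of the arrays, since 220 of 221 genes stayed called with it as a covariate. Alleles carried along with the edited Htt gene are not the source either, because without chromosome 5 the count was 72 against 26.5. Blocks of strain alleles that differ between the Q20 and Q111 mice, which have a mixed background, remain a candidate explanation, with Rpp25l, Dctn3, Ccl19 and Fancg on chromosome 4 as an example. An effect of the expanded allele itself stays open and untested, because the strain origin of each mouse is not labelled.

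In the interaction 58 of 73 genes had opposite signs of the 2 allele effects, which choosing genes by their difference favours, while 6 were called in both with opposite signs and 11 in neither. A mislabelled mGluR5 genotype is argued against by Grm5, whose gap of 0.678 between genotypes exceeded the largest range of 0.238 within them. A mislabelled Htt allele cannot be judged in this way, since the Htt gap of 0.020 was smaller than the largest range of 0.184 within an allele. The signal range of the arrays is argued against by the 73 of 73 genes that stayed called with the covariate. Strain alleles that fell differently into the 4 groups remain a candidate explanation, since 18 of the 73 had another such gene among 5 neighbours on either side against 3.09 in shuffles (permutation p = 1e-04, the smallest possible), and 11 against 2.95 without neighbours of the same name family (p = 0.003). A block of 10 tested genes on chromosome 18 held 7 of them, all protocadherins, which may share probes. A dependence of the Q111 effect on mGluR5 stays open and was not tested apart from these alleles.

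A pair of list shifts stands out in the average effects, that of vascular markers downward in Q111 mice and that of oxidative phosphorylation subunits upward without mGluR5, neither called with an estimated correlation (adjusted p = 0.725 and 0.994). The signal range of the arrays is argued against as their source, since both stayed called with it as a covariate (adjusted p = 6.95e-08 and 2.50e-06). Members that move together whatever the group remain a candidate explanation: of 100 groupings of the 12 arrays, 5 gave a p as small as the real one for the vascular markers, and 6 for the oxidative phosphorylation subunits, the real grouping included. The smallest p of another grouping was 3.66e-10 against 2.41e-06 in the first case and 8.72e-15 against 6.10e-10 in the second. A change in vessels or in mitochondria that follows the genotypes stays open and untested.

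The counts of called genes were set against other splits of the same arrays, the real split included. For the interaction 1 of 100 splits gave as many (73 against at most 8), and for the average effect of mGluR5 loss 1 of 100 (49 against at most 7). For the average effect of the Q111 allele 2 of 100 did (221 against at most 325). The other splits mix the genotypes, so differences between the groups enter their spread and can lower their calls. The comparison therefore cannot exclude chance for these 3 counts. The split with 325 kept 5 of the 6 Q111 arrays together and parted arrays of mean interquartile range 2.70 from arrays of 2.85, wider than the real 2.73 and 2.81. What gave it more calls was not tested. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real counts were 96 and 148 for the Q111 allele with and without mGluR5 and 93 for the double mutant, against 0 in each other split. They were 50 and 46 for mGluR5 loss in Q20 and Q111 mice, against at most 3 and 2, with 1 split of 10 reaching each.

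The number of shifted lists did not stand out in the same way. As many lists or more came from 92 of 100 splits for the interaction (1 list, at most 11 in another split), 77 for the average effect of the allele (2 lists, at most 11) and 27 for that of mGluR5 loss (6 lists, at most 10). Chance can account for these counts. With 10 splits each, too few for a share under 0.05, 5 reached the 3 lists of the allele with mGluR5 (at most 11), and 3 the 4 lists without it (at most 5). In the others 8 reached the 3 lists of mGluR5 loss in Q20 mice (at most 9), 6 the 2 lists in Q111 mice (at most 10) and 7 the 3 lists of the double mutant (at most 5).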

How the results depend on the processing

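The interquartile range as a covariate and the fit without the 2 arrays at the ends of the first principal component were chosen after the data were seen. Results are given in the order of the Q111 allele with mGluR5, without it, mGluR5 loss in Q20 mice, in Q111 mice, the interaction, the double mutant, the average effect of the allele and that of mGluR5 loss, where the counts of called genes were 96, 148, 50, 46, 73, 93, 221 and 49. Directions are compared where a call exists. Grm5 in the effects of mGluR5 loss and Htt in those of the allele kept their direction and their side of the threshold under every alternative run. The correlation between the effects of the allele ran from 0.108 to 0.371. Those between the effects of mGluR5 loss (-0.0578 to 0.0361) and between the average effects (-0.332 to 0.0877) changed sign in some alternatives, within the spread of regrouped arrays. Of 212 called values of named genes none changed sign in any alternative, although 94 were no longer called with an unmoderated model and 47 with all probe sets tested. Of the 212 named calls, 191 were still tested with the filter at the 50th percentile, and all 191 were kept. That filter removes the genes nearest to background, so it cannot show what background limits in them.

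Counts moved by more than 1.5 times as follows, and except where stated the cause was not tested. An unmoderated model gave 35, 91, 19, 23, 19, 40, 123 and 23. The authors' criteria gave 165 for the interaction and 51 and 17 for the averages. A fold minimum beside the adjusted p gave 84 for the allele without mGluR5 and 49 and 16 for the averages, since it removes smaller changes by construction. An intensity trend gave 84 and quantile normalization 76 for mGluR5 loss in Q20 mice, and the compared groups alone gave 47 for the allele with mGluR5. Array weights gave 44, 3270, 2120 and 25, then 819, 391 and 74 for the double mutant and the averages, with weights from 0.178 to 12.3, the highest for replicate 1 of the Q20 mice without mGluR5. All probe sets tested gave 218 and 261 for the allele, 223 for the double mutant and 461 for its average, because sets without a single gene were added. The covariate gave 266, 353, 213, 150, 153, 287, 488 and 170. Without the arrays at both ends of the first principal component the counts were 36, 230, 89, 19 and 33, and 132 and 30 for the averages. Median centring turned the split of the average effect of mGluR5 loss to 23 higher and 20 lower from 21 and 28.

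The replicate numbers do not pair the samples as far as the labels show. Still, 11 of 18 same-numbered pairs of arrays correlated above 0.1 after group means were removed (from -0.144 to 0.567), and 9 of 12 arrays correlated best with an array of their own number. Replicate 2 had the widest interquartile range (2.88, 2.95, 2.93 and 2.80) and the highest value of the first principal component within each of the 4 groups. The median of these correlations was 0.280 in same-numbered and -0.0849 in other pairs. The labels give no shared day or litter, and the main model held no term for the number. With the number as a block the counts were 204, 343, 129 and 103, then 215, 487 and 79 for the double mutant and the averages.

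Leaving out 1 array at a time gave 44 to 128 (47 and 44 without replicates 2 and 3 of the Q20 mice with mGluR5, 45 without replicate 1 of the Q111 mice with it). For the allele without mGluR5 it gave 74 to 232 (74 and 88 without replicates 1 and 2 of the Q20 mice without mGluR5, 80, 85 and 84 without replicates 1, 2 and 3 of the Q111 mice without it, 232 without replicate 2 of the Q111 mice with it). For mGluR5 loss in Q20 mice it gave 25 to 97 (30 and 25 without replicates 2 and 3 of the Q20 mice with mGluR5, 26 and 31 without replicates 1 and 2 of those without, 97 without replicate 2 of the Q111 mice with it), and in Q111 mice 28 to 52 (28 without replicate 2 of the Q111 mice without mGluR5). The interaction gave 34 to 69 (44 and 40 without replicates 2 and 3 of the Q20 mice with mGluR5, 34 without replicate 1 of those without, 42 without replicate 1 of the Q111 mice with it, and 46, 47 and 45 without replicates 1, 2 and 3 of those without). The double mutant gave 49 to 163 (55 and 49 without replicates 2 and 3 of the Q20 mice with mGluR5, 57 and 53 without replicates 2 and 3 of the Q111 mice without it, 163 without replicate 2 of the Q111 mice with it). The average effect of the allele gave 119 to 511. These were 126 and 137 without replicates 2 and 3 of the Q20 mice with mGluR5, 128 and 137 without replicates 1 and 2 of those without, 119 and 511 without replicates 1 and 2 of the Q111 mice with it, and 123, 138 and 143 without replicates 1, 2 and 3 of those without. That of mGluR5 loss gave 29 to 60 (31 without replicate 3 of the Q20 mice with mGluR5, 29 without replicate 1 of those without). Fewer arrays lower the power of each fit by construction, and the cause of the rise without replicate 2 of the Q111 mice with mGluR5 was not tested.

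The lists called numbered 3, 4, 3, 2, 1, 3, 2 and 6, and with an estimated correlation 0 in each. The block gave 1 for the allele with mGluR5, without myelin (adjusted p = 0.0609) and thalamus markers (0.0534), and 2 for the average of mGluR5 loss, without vascular, microglia, GABA and interferon genes (0.0592 each). The covariate gave 5 for the allele with mGluR5, 0 for the interaction and 3 for the average of mGluR5 loss. Without the arrays at both ends 1 list was called for the allele with mGluR5, 2 for the interaction and 1 for the average of the allele, and the myelin markers reversed in the allele with mGluR5 (adjusted p = 0.956, while its alternatives ran from 0.000902 to 0.999). Quantile normalization gave 2 for the allele without mGluR5 and 3 for the average of mGluR5 loss, and no filter gave 2 for the allele with mGluR5, 7 for mGluR5 loss in Q20 mice and 6 for the average of the allele. Single arrays left out gave 0 to 4, 2 to 5, 0 to 5, 1 to 3, 0 to 3, 3 to 4, 1 to 5 and 2 to 7 lists. For the neighbours of Grm5 in the average effect the Fisher p was 0.112, 0.0334 with 50 genes on either side, and from 0.0243, without replicate 3 of the Q111 mice with mGluR5, to 0.367 with 1 array left out.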

Other observations

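Markers of cells outside the main comparisons varied in single members, and the genes below were read after their values were seen unless the naming rule took them. The choroid plexus transport protein Ttr stood at -1.49 ± 0.52 (SE) log2 units for the Q111 allele without mGluR5 and 0.88 ± 0.52 for mGluR5 loss in Q20 mice, neither of which passed, with the widest error among the markers named. Of the microglia markers, Fcrls stood at -1.07 ± 0.25 for the allele without mGluR5 and Siglech at 0.30 ± 0.09, opposite in sign, and neither was called over all genes. Among glutamate receptors Grm8 stood at 0.40 ± 0.12 with mGluR5 and 0.21 ± 0.12 without it, without passing, beside the falls of Grm7.

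The respiratory chain held called members of both signs for the allele: in complex II Sdhc rose and Sdhd fell in the average effect (0.38 ± 0.07 and -0.33 ± 0.07). Each had a called neighbour, on chromosomes 1 and 9. For the allele with mGluR5 the complex I subunits Ndufa12 (-0.62 ± 0.17) and Ndufb10 (-0.48 ± 0.15) did not pass. Striatal interneuron markers included Slc17a8, which fell with mGluR5 (-0.52 ± 0.10), and Npy at 0.28 ± 0.10 and Htr3a at -0.45 ± 0.12 without it, which did not pass.

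The correlations between effects were set against 100 regroupings of the arrays. A correlation as large in absolute size as the 0.271 between the effects of the allele came from 31 of the 100, as the -0.0156 between the effects of mGluR5 loss from 97, and as the -0.0834 between the average effects from 78.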
